A study of Mus musculus with 16 samples.

How the data were processed

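The series holds 16 Affymetrix arrays of mouse endothelial cells that were derived from embryonic stem cells carrying a null VE-cadherin gene. Per the labels, the cells were VE-cadherin (VEC) negative or VEC positive and were sparse or confluent, which gives 4 conditions, and they were kept in serum-free medium with albumin for 36 h before lysis. Each condition was measured on both chip types of the MG_U74 set, MG_U74Av2 (chip A) and MG_U74Bv2 (chip B), starting from 15 µg of total RNA. Per the labels, each labelled cRNA sample was hybridised to 2 copies of each chip. The 2 arrays of a condition on a chip were therefore treated as technical copies of 1 cRNA sample, and tests between array groups compared these cRNA samples against the spread between hybridisations, not conditions across independent cultures.

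The deposited tables hold a linear intensity per probe set, the MAS5 signal, which the authors scaled to a target of 500 per array, per the labels and the submitters' processing notes. Every column was positive and had a trimmed mean between 500.1 and 500.3, leaving out 2% at each end. The series text also names a normalisation on the median over all samples, and this centring per gene was not seen in the tables. The tables carry no detection calls, and background correction and the summary of probe pairs were those of MAS5. Versions of the authors' software are not given in the sources used here. No column of another series was present (0 columns).

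Chip A had 12488 probe sets and chip B 12477, of which 66 on each were Affymetrix controls and were left out of the tests. Gene symbols came from the GEO platform annotation and were checked through Entrez identifiers against the RefSeq genes of mouse assembly GRCm38.p6, where 21411 probe sets matched and 0 symbols changed. Of 24833 probe sets other than controls, 21414 had 1 gene symbol, 574 had several and were not named, and 2845 had none. Where a gene had several probe sets, it was represented by its probe set on chip A before chip B, and then by the highest mean signal, and disagreeing probe sets are given in the text. Chromosomes are named from the same RefSeq table and no positions are printed.

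Signals were tested as log2(signal + 50), so that a fold given here is on the scale of the signal plus this offset and understates changes of dim genes. A probe set was kept if the mean log2 value of at least 1 group lay above the median of all probe sets of its chip (the 50th percentile, a signal of 160 on chip A and 231 on chip B), which left 6997 probe sets on chip A and 7304 on chip B, 14301 in all. Linear models were fitted for each chip over all 4 conditions with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean signal. The residual degrees of freedom were 4 per chip, and the prior added 5.65 on chip A and 5.62 on chip B. P values were adjusted by the Benjamini-Hochberg method over the kept probe sets of both chips, and a probe set passed at an adjusted p below 0.05 and a change of at least 1 on the log2 scale. Adjusted p values in the text are from these limma fits. The comparisons were VEC-positive against VEC-null cells when confluent and when sparse, confluent against sparse cells of each line, and the difference between the density responses of the lines (the interaction). The set of probe sets higher in confluent VEC-positive cells had to pass against each of the other 3 groups. A further fit averaged the copies and used the 4 cRNA samples as units, with VEC and density as additive terms, 1 residual degree of freedom per chip and a prior of 7.91 on chip A and 23.7 on chip B.

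A total of 24 gene lists was fixed before the data were examined, and those described here are adherens junction, tight junction, endothelial identity, Notch pathway, beta-catenin TCF targets, FoxO targets, TGF-beta and BMP pathway, cell cycle, CDK inhibitors and quiescence, extracellular matrix, matrix proteases and inhibitors, integrins and leukocyte adhesion, smooth muscle and fibroblast markers, embryonic stem cell markers, blood cell markers, epithelial and other germ layer markers, YAP and TEAD targets, interferon response, cholesterol synthesis, hypoxia and glycolysis, immediate early and stress, inflammatory cytokines and chemokines, and vascular growth factors and receptors. A list is described by the number of measured members that passed, over all probe sets and adjusted over the list alone, and by its median log2 change. The median has its percentile among 10000 random lists of the same size matched on mean level in 20 bins (random seed 1), as a description of these cRNA samples with no p value. Over 24 lists and 5 comparisons, 50 of 120 percentiles lay outside the range from 2.5 to 97.5. If the members of a list varied independently, like random genes, 6 would be expected. Members of a list can vary together, lists share genes and comparisons share arrays, so 50 against 6 does not measure the evidence for an effect.

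Genes named in the text follow a rule also fixed at that stage. It takes Cdh5 and Cldn5 in each comparison, the 10 genes with the largest rise and the 10 with the largest fall among genes that passed with array copies that do not overlap, up to 4 members of each list with the largest changes that passed, any measured member of the junction lists, and 20 genes of the set. Any other gene is said to have been chosen after its values were seen.

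The scripts were tested on simulated data made from the real levels and copy spread. For the VEC comparison in confluent cells, with 200 of 13389 probe sets changed, 85.6% were called at a simulated change of 1.5 and 97.9% at 3, with 2 unchanged probe sets called. Of the changed probe sets, 91.1% entered the simulated set with 0 unchanged ones. In 20 simulations without effects, at most 0 probe sets were called in any comparison and 0 in the set. Of random gene lists in simulated data without effects, 4% lay outside the middle 95% of other random lists. These were not matched on level and the simulated genes varied independently, so the matched percentiles themselves were not tested. For the additive fit with a simulated spread between cultures of 0.2, over 13865 probe sets, 87.5% were called at 1.5 and 91.4% at 3, with 9 unchanged ones called. These simulated VEC changes were equal at both densities, with no density effect and no interaction. In the measured data 1745 probe sets passed the interaction, which this fit takes as error, so its recovery there may be lower.

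Precision is limited by the number of arrays. The median absolute difference between copies was between 0.128 and 0.207 on the log2 scale. Alternatives covered the offset (none, 16 and 200), quantile normalisation and median centring, the level filter (none and the 75th percentile), the variance trend, the thresholds (adjusted p alone, and a minimum fold of 1.5), each chip alone, the mean over all probe sets of a gene, fits of only the groups compared, the replicate number as a block, leaving out each array copy, and a call without a test. Leaving out the genes of 4 chromosomes, together with probe sets that had no chromosome assigned, was added after the data were seen.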

Results

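Transcript levels were measured in cultured mouse endothelial cells that differed in VE-cadherin (VEC, encoded by Cdh5), the cadherin of endothelial adherens junctions, and in density. VEC-null and VEC-positive cells were each taken when sparse, with few contacts between cells, and when confluent. Both lines were described with the same embryonic stem cell origin, and how the VEC-positive cells came to express VEC is not given in the sources used here. Each of the 4 conditions was represented by 1 cRNA sample, hybridised to 2 copies of chip A and 2 copies of chip B, which makes 16 arrays. Values below are MAS5 signals, given as mean ± SD over n = 2 array copies, and log2 changes on the scale of the signal plus an offset of 50 with their standard error (SE). The p values measure only the spread between copies of the same cRNA sample, which is technical, and do not cover differences between cultures. The series text asks which genes rise with VEC when it is clustered at junctions, that is in confluent VEC-positive cells, and the density and VEC comparisons below describe the 4 conditions behind that question.

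Copies of the same sample correlated across probe sets with r between 0.951 and 0.989. The median signal per array was 139.8 to 174.1 on chip A and 223.2 to 251 on chip B. The 3'/5' signal ratio of the control probe sets, a sign of RNA integrity, was 0.903 to 1.23 for Gapdh and 1.11 to 1.33 for actin. In confluent VEC-positive cells the Gapdh ratio was 1.23 and 1.14 on chip B, where no other array was above 1, but 1.01 and 0.968 on chip A, where another array had 0.987. Their actin ratio was 1.33 and 1.26 on chip A, where no other array was above 1.25, but 1.21 and 1.28 on chip B, where sparse VEC-positive cells had 1.31 and 1.26. The confluent VEC-positive arrays had the lowest Gapdh control signals, 12920 and 12788 on chip A against 16729 to 21421 on the other arrays of that chip. On chip B they had 29270 and 28590 against 36572 to 55583. Their actin control signals were also the lowest, 19212 and 19634 against 23086 to 30459 on chip A. On chip B the actin signals were 39700 and 44001 against 58107 to 69054.

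Cdh5, the targeted gene, was detected at similar levels in both lines. Its single probe set gave a signal of 1268 ± 19 in sparse and 2608 ± 140 in confluent VEC-null cells, and of 1399 ± 92 in sparse and 2566 ± 58 in confluent VEC-positive cells. The VEC-positive cells differed from the VEC-null cells by a log2 change of -0.02 (SE 0.09, limma adjusted p 0.87) when confluent and 0.13 (SE 0.09, limma adjusted p 0.26) when sparse. Which part of the gene was deleted is not given in the sources used here, so this probe set does not check the labels.

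Cldn5, the endothelial claudin of tight junctions, was among the genes with the largest rises in confluent VEC-positive over confluent VEC-null cells. The Cldn5 signal was 5115 ± 150 in confluent VEC-positive and 50.5 ± 39 in confluent VEC-null cells, a log2 change of 5.74 (SE 0.27, 53.4-fold, limma Benjamini-Hochberg adjusted p 7.6e-07). Vwf, which encodes von Willebrand factor, was at 2516 ± 110 against 21.95 ± 2.1, a log2 change of 5.16 (SE 0.16, 35.7-fold, limma adjusted p 9.6e-08). Col5a2, a fibrillar collagen chain, was 41.8-fold higher at 3099 ± 240 against 27.2 ± 25. The order of these 3 genes depends on the offset, and without it the log2 change was largest for Col5a2. In the other direction, Gja1, the gap junction protein connexin 43, was at 21 ± 18 against 2289 ± 27, a log2 change of -5.07 (SE 0.16, 33.5-fold lower), and its other probe set gave -1.97. Pmepa1 was 65.4-fold lower by its representative probe set, while another gave a log2 change of -1.77, and the transcription factor Sox11 was 37.1-fold lower.

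**Figure D1:**
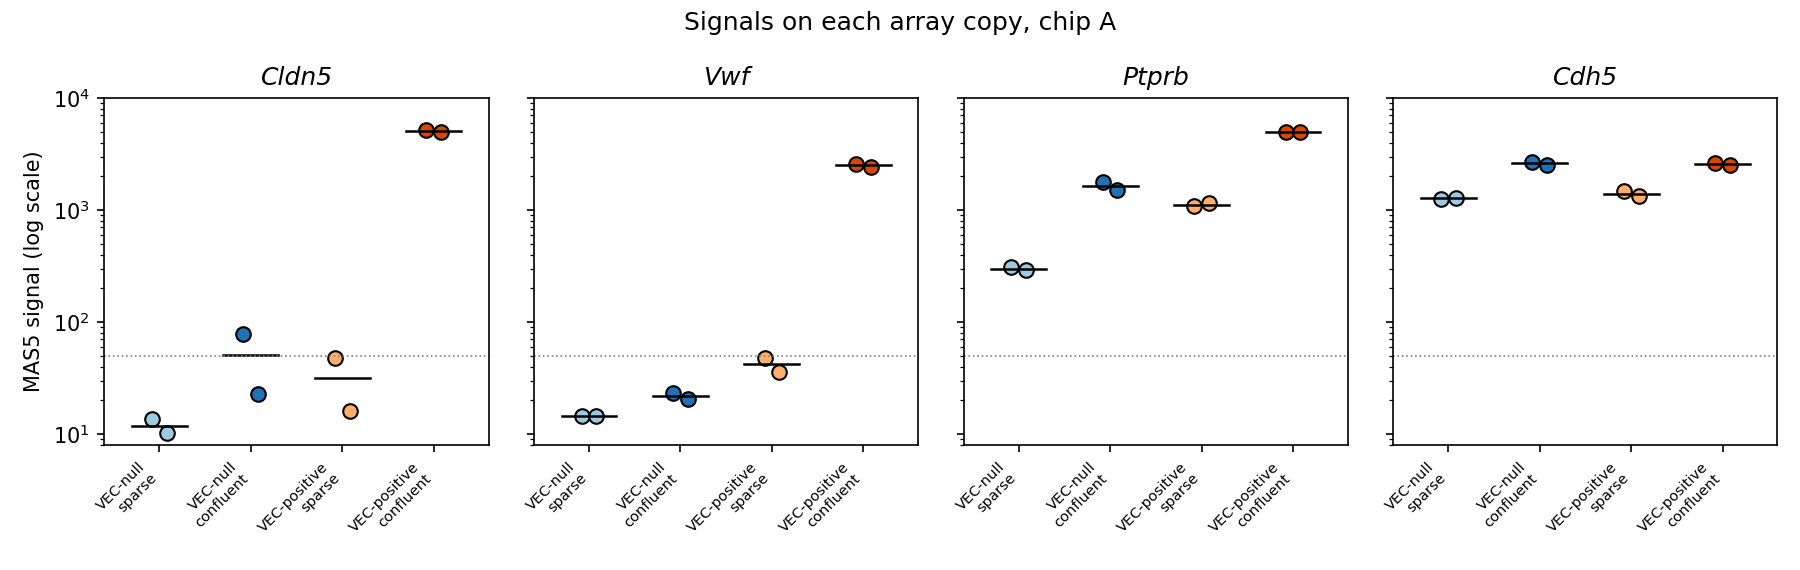
MAS5 signal (log axis) of Cldn5, Vwf, Ptprb and Cdh5 on chip A in each of the 4 conditions, where points are the 2 array copies, horizontal lines are their means and the dotted line is the offset of 50 added before taking logs. Cldn5 and Vwf lie at or below 78 on each array except those of confluent VEC-positive cells, where they reach 5115 and 2516 on average, while Cdh5 lies at 2608 and 2566 in both confluent groups.

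The other genes with the largest rises in confluent VEC-positive cells were Ak1 (24.1-fold), Gatm (21.9-fold), Lamb3, a laminin chain (21.7-fold), H1f10 (16-fold), the urea transporter Slc14a1 (15.8-fold), Sned1 (14.7-fold) and AU021092 (12.9-fold). The H1f10 rise rests on the representative probe set, and another probe set of H1f10 gave a log2 change of 0.01. The other probe set of Lamb3 gave 2.54, and those of Sox11 gave -3.54 and -1.98. The other largest falls were the imprinted gene Mest (21.2-fold), the collagen Col3a1 (16.5-fold), Btnl9 (15.6-fold), the matrix protein Postn (12.8-fold), Igfbp3 (12.1-fold), Adamtsl1 (11.1-fold) and Oasl1 (10.6-fold). Among these 20 genes the SE was 0.14 to 0.35, and the largest limma adjusted p was 4.3e-05.

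Of 19 measured adherens junction genes, 2 were higher in confluent VEC-positive cells, 0 were lower and 17 did not pass. Ptprb, the phosphatase VE-PTP that associates with VEC, changed by 1.57 on the log2 scale, and the nectin gene Nectin1 by 1.16. The catenin genes Ctnnb1, Jup, Ctnna1 and Ctnnd1 did not pass, with log2 values of -0.36, 0.11, 0.26 and 0.16. Of 11 tight junction genes, 3 were higher and 8 did not pass, the 3 being Cldn5, Cgnl1 (log2 1.33) and Jam3 (log2 1.16), while the list median was -0.01 (percentile 54.2). Tjp1, which encodes ZO-1, gave -0.75 and Esam -0.20 without passing. Of 33 endothelial identity genes, 4 were higher, namely Vwf, Mmrn2 (log2 3.16), Edn1 (1.49) and Acvrl1 (1.02), 0 were lower and 29 did not pass, and the list median was -0.06 (percentile 34.4). Of 11 CDK inhibitor and quiescence genes, 5 were higher and 6 did not pass, with the largest log2 changes in Cdkn1a (3.28), which encodes p21, Gas6 (2.88), Btg2 (1.5) and Rb1 (1.23). Of 29 cell cycle genes, 1 was higher (Cdk1 1.17), 0 were lower and 28 did not pass, and the list median of 0.40 lay at percentile 100.

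Notch pathway genes were lower in confluent VEC-positive cells for 4 of 12 measured members, 0 were higher and 8 did not pass. The log2 changes were -3.0 for the ligand Dll4, -1.56 for Nrarp, -1.46 for Notch3 and -1.11 for Hey1, and the list median of -0.62 lay at percentile 0 of matched random lists. Cholesterol synthesis genes were lower for 6 of 17 members, led by Fdps (-2.16), Srebf1 (-1.90), Idi1 (-1.74) and Lss (-1.41), with 11 not passing and a median of -0.74 at percentile 0. Extracellular matrix genes went both ways, with 4 higher, 7 lower and 15 of 26 not passing. Their largest log2 changes were those of Col5a2 (5.39), Col3a1 (-4.04), Postn (-3.68) and Bgn (3.51). Of 23 vascular growth factor and receptor genes 1 was higher, 4 were lower and 18 did not pass, among them Efna1 at -1.90 and placental growth factor Pgf at -1.87, and the median was -0.34 at percentile 0.2. Of 15 cytokine and chemokine genes 5 were lower, 0 were higher and 10 did not pass, led by Ccl2 (-2.22) and Il6 (-1.72), with a median of -0.48 at percentile 0.2. Matrix proteases and inhibitors had 3 lower members (Plat -2.09, Mmp13 -1.68, Plaur -1.63), 0 higher and 8 of 11 not passing.

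Interferon response genes were lower in 3 of 33 members (Isg15 at -2.60, Ifit2 at -1.24 and Oasl2 at -1.20), with 30 not passing and a median of -0.33 at percentile 0.1. Of 15 FoxO targets, 2 were higher (Sesn1 1.92, Klf4 1.16) and 13 did not pass, and of 11 beta-catenin TCF targets, 1 was higher (Ccnd1 1.45), 2 were lower (Apcdd1 -1.98, Myc -1.15) and 8 did not pass. The TGF-beta and BMP list had 3 higher and 2 lower members of 18, including Ltbp1 (1.62) and the BMP target Id3 (-1.99), and 13 did not pass. Integrin and leukocyte adhesion genes had 3 higher and 3 lower members of 19, with Itgb4 at 2.41 and Itga2 at -1.18, and 13 did not pass. Of 7 measured smooth muscle and fibroblast markers, 2 were higher (S100a4 1.18, Dcn 1.18), 2 were lower (Pdgfrb -2.65, Acta2 -1.64) and 3 did not pass. Cd68 (-1.5) was the only 1 of 3 measured blood cell markers to pass. Gata4 (1.10) was the only 1 of 7 epithelial and other germ layer markers to pass, and the only measured embryonic stem cell marker, Fgf4, did not pass in any of the 5 comparisons (0.09 here). YAP and TEAD targets had 1 higher (Ccn2 1.98) and 1 lower member (F3 -2.02) of 11. Hypoxia and glycolysis had 1 lower member of 19 (Hk1 -1.80) with a list median of -0.47 at percentile 0, and immediate early and stress genes had 2 higher (Hspa1b 1.39, Hspa1a 1.38) and 2 lower (Dusp6 -1.60, Trib3 -1.09) of 23 (median -0.33, percentile 0.2). For each list in this comparison, the counts adjusted over the list alone were the same as those over all probe sets.

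In all, 614 probe sets (498 genes) were higher and 517 (408 genes) were lower in confluent VEC-positive than in confluent VEC-null cells, 1131 of 14301 tested. The number fell to 590 with an offset of 200 and to 699 with a level filter at the 75th percentile, so that part of it rests on dim probe sets. Genes of some chromosomes (RefSeq table of assembly GRCm38.p6) shifted together between the lines. The median log2 change of VEC-positive against VEC-null cells, averaged over both densities, was 0.43 for 436 genes of chromosome 10, 0.25 for 509 genes of chromosome 8, 0.21 for 314 genes of chromosome 14 and -0.36 for 574 genes of chromosome 5. Chromosomes 18 (-0.18), 19 (-0.17) and 3 (-0.13) shifted less, and each of these 7 chromosomes had an adjusted shuffle p of 0.00029 (Benjamini-Hochberg over 20 chromosomes, permutation of genes), where the unadjusted p of 1e-04 is the smallest the shuffles can give. The shuffles take genes as independent, although neighbouring genes were correlated, so this p may be too small. It does not cover differences between cultures. Chromosome medians of the density comparisons were 0.12 or less in size on each chromosome, which is close to the size for chromosome 3. Ptprb, Cdk1, Dcn, Madcam1, Igf1 (log2 1.06) and Gpr182 (log2 1.22) lie on chromosome 10. There, by a split chosen after the values were seen, 316 genes after the first 120 in order had a median of 0.63 in confluent cells. Less that median, none of these named genes would reach the threshold of 1. The same holds for Gata4 on chromosome 14 (median 0.23) and Oasl2 on chromosome 5 (median -0.31) in confluent cells, and for Mcm7 on chromosome 5 (median -0.34) in sparse cells. On chromosomes 5, 8, 10 and 14, 11.8% of genes passed in confluent and 14.5% in sparse cells, against 7.09% and 9.15% of genes elsewhere, where chromosomes 3, 18 and 19 are counted. Without the 4 chromosomes and the probe sets that had no chromosome assigned, 10338 probe sets were tested. Of these, 708 passed in confluent and 912 in sparse cells, so the drop is not due to the 4 chromosomes alone.

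**Figure D2:**
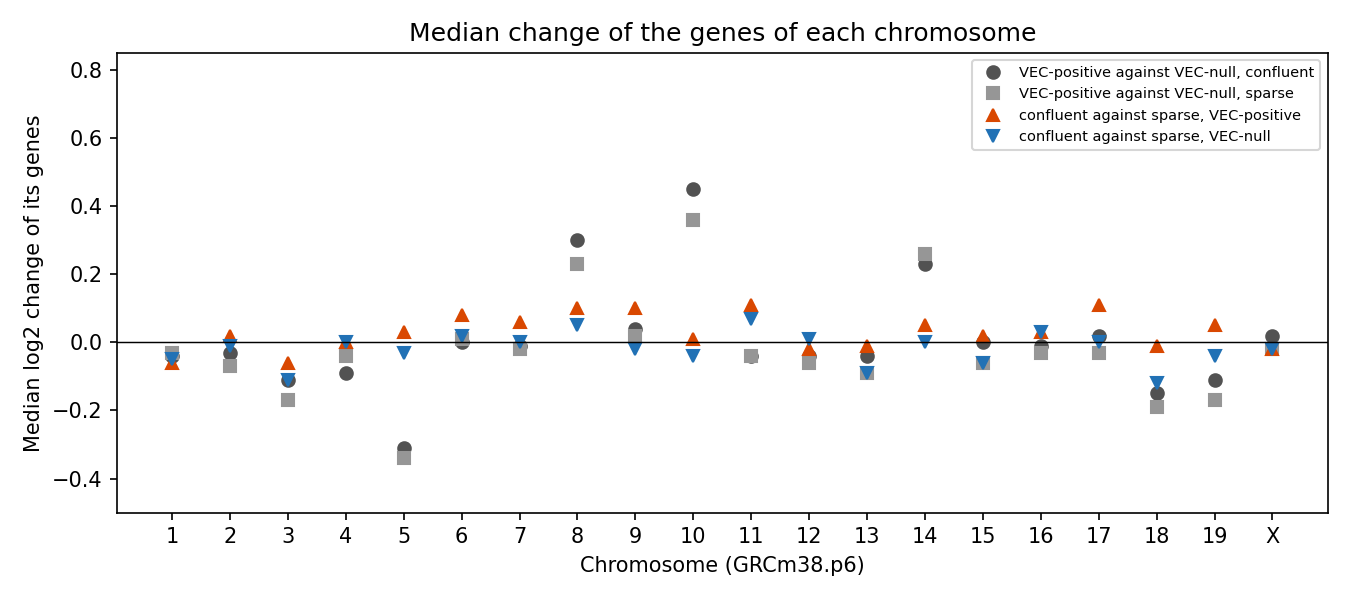
Median log2 change of the measured genes of each chromosome (x axis) in the 2 VEC comparisons and the 2 density comparisons, each a point per chromosome. Chromosome 10 lies at 0.45 in confluent and 0.36 in sparse cells and chromosome 5 at -0.31 and -0.34, while the density comparisons stay within 0.12 of 0.

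Sparse VEC-positive cells differed from sparse VEC-null cells in partly other genes. Cldn5 was low in both, at 31.9 ± 22 and 11.9 ± 2.4, and the difference did not pass (log2 0.38, SE 0.27, limma adjusted p 0.30). The largest rises were again in Col5a2, at 4707 ± 280 against 31.15 ± 7.1 (log2 5.88, SE 0.19, 58.7-fold, limma adjusted p 1.6e-07), and in the adenylate kinase gene Ak1 (36.4-fold). Krt19, an epithelial keratin, was at 904.7 ± 61 in sparse VEC-positive cells and between 3.9 ± 0.85 and 5.6 ± 2 in the other 3 groups. Gja1 showed the largest fall, from 7955 ± 74 to 23.7 ± 2.3 (log2 -6.76, SE 0.16, 109-fold lower, limma adjusted p 2.4e-08), with -4.72 by its other probe set.

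The remaining largest rises in sparse VEC-positive cells were Apbb1ip (17.7-fold), Ddit4l (16.7-fold), Nrn1 (16.6-fold), the actin-severing protein gelsolin Gsn (14.5-fold), cyclin D2 Ccnd2 (13.7-fold), Anxa8 (13.5-fold) and Stfa3 (13.4-fold). The falls were led by Oasl1 (29.8-fold), Pmepa1 (25.8-fold), Sox11 (21.7-fold), the chemokine Ccl5 (9.99-fold), Ifit1 (9.89-fold), the transporter Slc6a15 (9.54-fold), Mest (8.65-fold), Wtip (8.51-fold) and Rsad2 (8.41-fold). For Pmepa1 another probe set gave a log2 value of 0.17. Oasl1, Ifit1 and Rsad2 are interferon-induced genes. Among the 20 genes the SE was 0.12 to 0.36 and the largest limma adjusted p was 4.8e-05.

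Interferon response genes were lower in sparse VEC-positive cells for 7 of 33 members, with 1 higher and 25 not passing, and the largest log2 changes were those of Ifit1 (-3.31), Cxcl10 (-3.05), Oasl2 (-2.74) and Gbp3 (-2.01). Of 15 cytokines and chemokines, 6 were lower, 3 were higher and 6 did not pass, with Ccl5 at -3.32 and Cxcl5 at -2.33. Cell cycle genes were lower for 4 of 29 members, Cdc6 (-1.5), Mcm7 (-1.24), Mcm3 (-1.20) and Mcm4 (-1.0), with 25 not passing and a list median of -0.62 at percentile 0. Matrix proteases and their inhibitors were higher for 6 of 11 members, including Adam15 (1.73), Timp1 (1.72), Timp3 (1.59) and Timp2 (1.56), with 5 not passing and a median of 1.06 at percentile 100. Extracellular matrix genes were higher for 7 of 26 members and lower for 0, with Fbln2 at 2.12, Tnc at 1.95 and the basement membrane collagen Col4a2 at 1.58. Cholesterol synthesis genes were higher for 4 of 17 members (Mvd 1.61, Fdft1 1.39, Nsdhl 1.32, Msmo1 1.24), and 13 did not pass.

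Of the 19 adherens junction genes, 4 were higher and 15 did not pass, the 4 being plakoglobin Jup (2.20), Ptprk (1.88), Ptprb (1.74) and Nectin1 (1.01). In the tight junction list Cgnl1 (1.49) was higher and the other 10 did not pass. Endothelial identity genes were higher for 6 of 33 members, with Mmrn2 at 1.89, Tie1 at 1.37, Cd93 at 1.24 and Emcn at 1.14, and 27 did not pass. Cdkn1a (2.37), Btg2 (2.06) and Gas6 (1.85) were higher among the CDK inhibitor genes and Cdkn1c (-1.29) was lower. Of the epithelial and other germ layer markers, Krt19 and nestin Nes (1.67) were higher and 5 of 7 did not pass. Among the smooth muscle and fibroblast markers S100a4 (2.99) and Dcn (1.75) were higher, and Snai2 (-1.35) and Acta2 (-1.20) were lower. Counts adjusted over the list alone were the same for each list.

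In total 777 probe sets (621 genes) were higher and 611 (519 genes) lower in sparse VEC-positive cells, 1388 of 14301 tested, and 689 passed with an offset of 200. Between the densities, 222 probe sets were higher in VEC-positive cells at both, where 33.4 are expected of independent lists, and 122 were lower at both, where 22.1 are expected. The VEC effects at the 2 densities correlated with r 0.356 across probe sets, which are not independent replicates. Of 367 probe sets that passed at both densities, 344 went the same way and 23 opposite ways.

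Confluence in VEC-positive cells went with rises past the threshold in 15 of 33 endothelial identity genes (2 fell) and 23 of 33 interferon response genes (1 fell). Of 17 cholesterol synthesis genes, 13 fell and 0 rose. Cldn5 rose from 31.9 ± 22 to 5115 ± 150 (log2 6.01, SE 0.27, 64.3-fold, limma adjusted p 1.5e-07). Vwf rose 27.9-fold, the phosphodiesterase Pde2a 26.7-fold to a signal of 13180 ± 490, and the orphan receptor Gpr182 29.6-fold. The largest falls were those of mesothelin Msln, from 3386 ± 170 to 33.2 ± 25 (42.3-fold), and of follistatin Fst, from 5894 ± 180 to 105 ± 13 (38.4-fold). Cdh5 itself gave a log2 change of 0.85 (SE 0.09), under the threshold of 1.

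The other largest rises with density in VEC-positive cells were Col23a1 (33.9-fold), neurotensin Nts (28.3-fold), Ushbp1 (28-fold), Gem (24.6-fold), the glutamate receptor subunit Gria2 (24.1-fold) and Oasl2 (23.7-fold). The other largest falls were Cobl (23.1-fold), the phosphatase Dusp5 (18.6-fold), farnesyl diphosphate synthase Fdps (17.7-fold), the neurotrophin Bdnf (17.3-fold), Krt19 (17.2-fold), Ccn2 (16.4-fold), Ankrd1 (16.1-fold) and Idi1 (14.1-fold). Another probe set of Cobl gave a log2 value of -0.34, and another of Fst gave -2.31. The SE of the 20 genes was 0.09 to 0.34 and the largest limma adjusted p was 7.3e-06.

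Interferon response genes rose for 23 of 33 members with density in VEC-positive cells, 1 fell and 9 did not pass, with a list median of 1.53 at percentile 100. Examples are Oasl2 (4.56), Ifit1 (4.30), Gbp3 (4.02) and Ifit3 (3.69). Vascular growth factors and receptors rose for 15 of 23 members and fell for 3 (median 1.30, percentile 100), among them Igf1 (4.19), the angiopoietin receptor Tek (2.85), the VEGF receptor Kdr (2.78) and, falling, Sema3c (-3.26). Endothelial identity genes rose for 15 of 33 members and fell for 2, with 16 not passing and a median of 0.98 at percentile 100, including Sox18 (4.54), Mmrn2 (3.34) and Ramp2 (3.19). Tight junction genes rose for 3 of 11 members, Cldn5, Jam3 (2.31) and Esam (1.82), and 8 did not pass. Adherens junction genes rose for 3 of 19 (Ptprb 2.10, Jup 1.40, Ptprm 1.32) and fell for 3 (Ptprk -1.99, Actn1 -1.60 and N-cadherin Cdh2 -1.29).

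Cholesterol synthesis genes fell for 13 of 17 members with density in VEC-positive cells, with 0 rising, 4 not passing and a median of -2.22 at percentile 0. The largest falls were in Fdps (-4.14), Idi1 (-3.81), Msmo1 (-3.62) and Lss (-3.30). Hypoxia and glycolysis genes fell for 12 of 19 and rose for 1 (median -1.21, percentile 0), with hexokinases Hk2 at -2.83 and Hk1 at -2.30, and immediate early and stress genes fell for 10 of 23 (median -0.90, percentile 0), with Ier3 at -3.12 and Chac1 at -2.12. YAP and TEAD targets fell for 5 of 11 and rose for 0 (median -0.44, percentile 3.5), led by Ccn2 (-4.04), Ankrd1 (-4.01) and Ccn1 (-3.55), and beta-catenin TCF targets fell for 4 of 11, Cd44 (-2.71), Myc (-2.55), Fosl1 (-2.52) and Ccnd1 (-1.76). In the TGF-beta and BMP list 7 of 18 members fell and 4 rose, with Inhba at -2.76, Bmp4 at -2.69 and Tgfb1 at 1.90. None of 29 cell cycle genes passed in this comparison with limma, 0 rising and 0 falling, while 20 had an unadjusted p under 0.05 and their median of 0.37 lay at percentile 99.6. The list counts adjusted over the list alone were again the same.

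In VEC-positive cells 1163 probe sets (910 genes) rose with density and 1031 (793 genes) fell, 2194 of 14301 tested, and 1305 passed with an offset of 200.

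Confluence in VEC-null cells went with rises past the threshold in 21 of 33 endothelial identity genes (2 fell) and 25 of 33 interferon response genes (1 fell). Of Notch and extracellular matrix genes, 8 of 12 and 10 of 26 rose and 0 fell. Cldn5 and Vwf stayed low. Sox18, an endothelial transcription factor, rose from 294.7 ± 9.5 to 12420 ± 590 (log2 5.18, SE 0.09, 36.2-fold, limma adjusted p 1.2e-09), and the gluconeogenic enzyme Fbp1 from 34.3 ± 18 to 4234 ± 670 (51.1-fold). Cldn5 did not pass, at 11.9 ± 2.4 in sparse and 50.5 ± 39 in confluent cells (log2 0.64, SE 0.27, limma adjusted p 0.075). Ccn2, a matricellular YAP target, fell from 6631 ± 800 to 138.2 ± 2.1 (log2 -5.14, SE 0.13, 35.4-fold lower). Cdh5 rose 2.01-fold (log2 1.01, SE 0.09, limma adjusted p 1.1e-05).

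Further large rises in VEC-null cells were Ushbp1 (29.7-fold), Slc7a7 (24.4-fold), Nts (24.3-fold), Slfn2 (22.9-fold), Myzap (21.2-fold), nidogen 2 Nid2 (20.8-fold), the acute phase gene Saa3 (20.3-fold) and Igfbp3 (18.7-fold). Further large falls were Ankrd1 (17.7-fold), Ccn1 (13.8-fold), Bcat1 (13-fold), Cited2 (12.6-fold), Cobl (12.5-fold), Sprr1a (11.9-fold), Otud1 (11.4-fold), Atic (10.9-fold) and the AP-1 gene Fosl1 (9.66-fold). Another probe set of Cobl gave a log2 value of -0.58. The SE of these genes was 0.09 to 0.32 and the largest limma adjusted p was 2.5e-06.

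Endothelial identity genes rose for 21 of 33 members in VEC-null cells and fell for 2 (median 1.40, percentile 100), with Tie1 at 3.32, Tek at 3.05 and Icam2 at 2.91. Interferon response genes rose for 25 of 33 and fell for 1 (median 1.53, percentile 100), with Ifit3 at 3.81 and Iigp1 at 3.43. Vascular growth factors and receptors rose for 17 of 23 and fell for 1 (median 1.95, percentile 100), with Igfbp3 at 4.23 and Igf2 at 3.35. Notch pathway genes rose for 8 of 12 and fell for 0 (median 1.2, percentile 100), namely with log2 changes of 3.32 for Dll4, 2.88 for Dll1, 2.51 for Notch4 and 2.31 for Notch1. Extracellular matrix genes rose for 10 of 26 and fell for 0, including Nid2 (4.38), Postn (3.63) and Col6a2 (2.68), and matrix proteases and inhibitors rose for 7 of 11 and fell for 1, with the collagenase Mmp13 at 3.99 and Mmp14 at 2.80. Tight junction genes rose for 5 of 11 and fell for 1, with Esam at 2.67, Jam2 at 2.47, Jam3 at 1.52 and Tjp1 at 1.32 rising and Cgn falling at -1.06.

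Cell cycle genes fell for 6 of 29 members in VEC-null cells, with 23 not passing and a median of -0.80 at percentile 0. The falls were largest for Bub1 (-1.53), Aurka (-1.37), Nek2 (-1.29) and Cdc20 (-1.24). Cholesterol synthesis genes fell for 5 of 17 (median -0.54, percentile 0.5), with Cyp51 at -1.73 and Fdps at -1.54. Immediate early and stress genes fell for 11 of 23, with the heat shock genes Hspa1b at -2.70 and Hspa1a at -2.39, and YAP and TEAD targets fell for 4 of 11 and rose for 1 (median -0.21, percentile 22.6). For each list here the counts adjusted over the list alone were unchanged.

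In VEC-null cells 1298 probe sets (981 genes) rose with density and 1058 (857 genes) fell, 2356 of 14301 tested, and 1444 passed with an offset of 200. The balance of rises and falls depends on the scaling, since median centring gave 1146 rising and 1272 falling in VEC-null and 1098 rising and 1169 falling in VEC-positive cells. In both lines 629 probe sets rose, where 106 are expected of independent lists, and 402 fell, where 76.3 are expected. The density effects correlated with r 0.613 across probe sets.

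**Figure D3:**
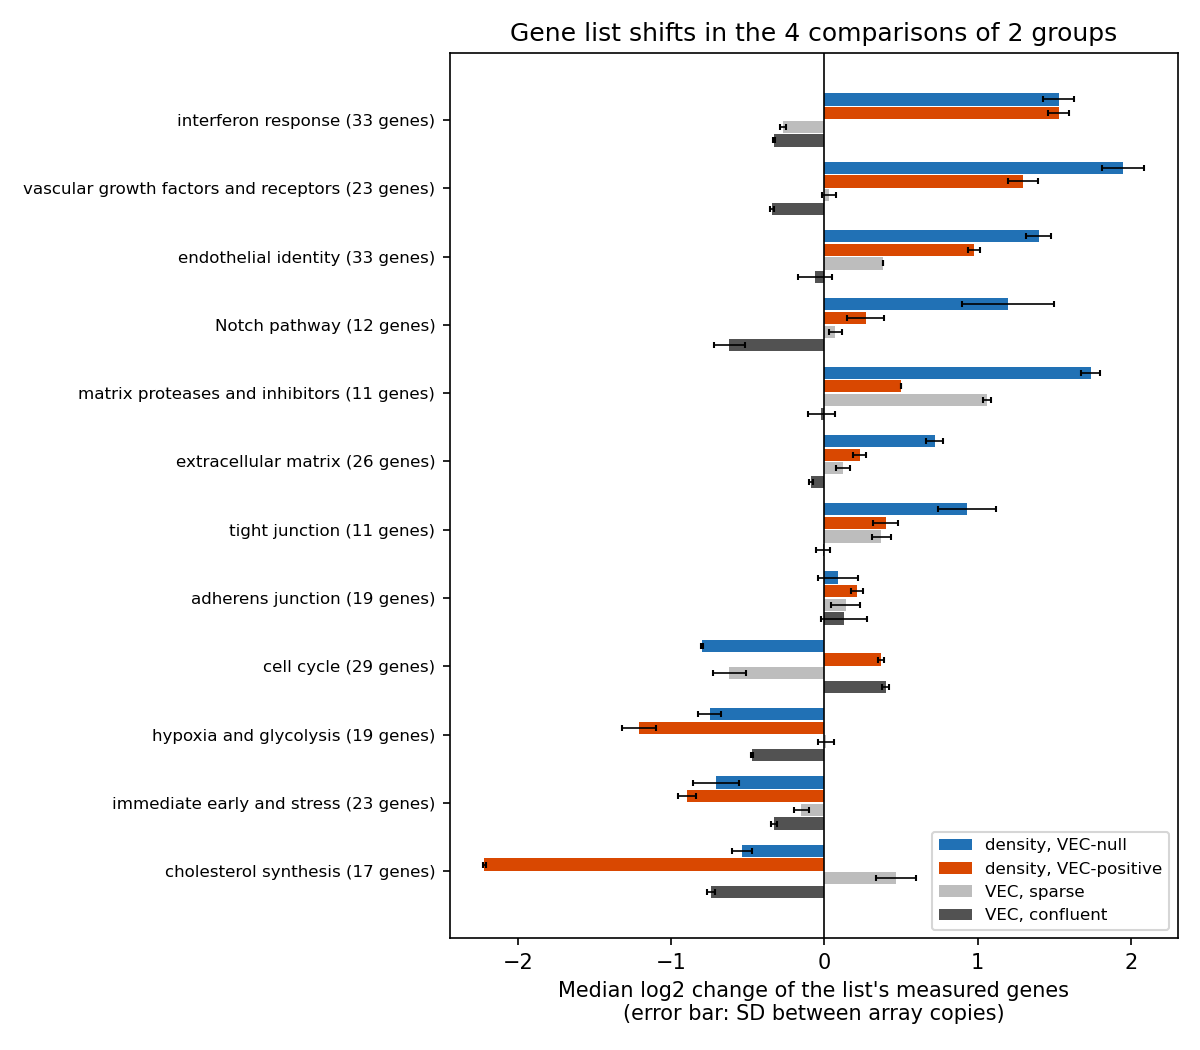
Median log2 change (x axis) of 12 of the gene lists (y axis, with the number of measured genes) in the density comparison of each line and the VEC comparison at each density, with error bars giving the SD between array copies. The cell cycle list lies at 0.37 with density in VEC-positive and -0.80 in VEC-null cells, and the cholesterol synthesis list at -2.22 and -0.54.

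A set of 189 probe sets, representing 152 genes, was higher in confluent VEC-positive cells than in each of the other 3 groups, and 97 probe sets (78 genes) were lower than in each. Cldn5 and Vwf led the set, with smallest log2 changes against the other groups of 5.74 and 4.80. They were followed by Lamb3 (3.99), the G protein regulator Rgs2 (3.39), the phosphatase Ptprv (3.25), multimerin 2 Mmrn2 (3.16), biglycan Bgn (3.10), Ahrr (2.80), Castor1 (2.69), the interleukin receptor Il13ra2 (2.51), Slc14a1 (2.47), Sned1 (2.38), the growth factor Gas6 (2.38), Col23a1 (2.33), Vwa1 (2.31), Col15a1 (2.16), Ebi3 (2.14), beta-arrestin Arrb1 (2.12), Cd200 (2.10) and Arhgef10l (2.08). Mmrn2 was at 11459 in confluent VEC-positive cells and at most 1247.8 elsewhere. A second, dim probe set of Vwf that did not pass the level filter gave 140.4 and 36.2 on the confluent VEC-positive copies, and 27.6 or less on each other array.

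From the lists, the set held Ptprb of the adherens junction, Cldn5 and Jam3 of the tight junction, Mmrn2 and Vwf of endothelial identity, Bgn, Col15a1 and Eln of the matrix, Itgb4 and Madcam1 of the adhesion list, and Sesn1, Tgfbi, Gas6 and Igf1. Of these, Ptprb, Madcam1 and Igf1 would not reach the threshold in confluent cells less the chromosome 10 median given above. It held 0 of 29 cell cycle, 0 of 12 Notch and 0 of 33 interferon response genes. Ptprb rose with density in both lines and was higher in VEC-positive cells at both densities, at 299.3 and 1646.8 in sparse and confluent VEC-null cells and 1118.9 and 4960.6 in sparse and confluent VEC-positive cells. The genes lower than in each other group included 5 of 17 cholesterol synthesis genes. Fdps fell by at least 2.16 on the log2 scale against each group, and Basp1 (-2.48), Dusp5 (-2.26), Bhlhe40 (-1.74), Idi1 (-1.74) and Acta2 (-1.64), chosen after their values were seen, were among the others. An offset of 200 left 109 probe sets in the set higher than each other group, and a filter at the 75th percentile left 114. Of its genes with their representative probe set in the set, 16 lie on chromosome 10, 16 on chromosome 8, 15 on chromosome 9 and 13 on chromosome 11, with 5 on chromosome 5 and 4 on chromosome 14. Without the 4 chromosomes whose median differed most between the lines, and without probe sets that had no chromosome assigned, the set held 123 probe sets.

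The response to density differed between the lines for 1745 probe sets, where the interaction is positive if a gene rose more, or fell less, in VEC-positive cells. It was 5.36 for Cldn5 (SE 0.38, limma adjusted p 2.6e-05), 4.65 for Vwf and 4.35 for Lamb3. Postn, Col3a1 and Gja4 (connexin 37) had negative values of -3.54, -3.34 and -3.35, since Postn rose from 10.95 ± 4.9 to 704.9 ± 1.6 and Gja4 from 12.2 ± 2.3 to 661 ± 18 in VEC-null cells and both stayed at or below 24.55 ± 8.8 in VEC-positive cells. Btnl9 showed the most negative interaction (-4.27, SE 0.50), with 985.4 ± 72 in confluent VEC-null cells and at most 23.15 ± 20 elsewhere, and Krt19 followed (-4.12).

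Further positive interactions among the 10 largest were Zfp428 (3.45), Bgn (3.38), the interleukin 1 receptor Il1r1 (3.35), Ahrr (3.29), Ptprv (3.19), Ifit1 (3.09) and Rgs2 (3.07). Further negative ones were Adamtsl1 (-3.70), Upp1 (-3.57), Anxa8 (-3.30), Stfa3 (-3.29) and Serpina3n (-3.22). The other kept probe set of Upp1 gave 0.69, and those of Ptprv gave 0.87 and 1.22. The SE of the 20 genes was 0.16 to 0.51 and the largest limma adjusted p was 0.0014.

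Cell cycle genes had a positive interaction in 16 of 29 members and a negative one in 0, with a median of 1.04 at percentile 100. The mitotic checkpoint kinase Bub1 had 1.93, with a mean signal of 1535.6 and 500.05 in sparse and confluent VEC-null cells and of 745.9 and 997.65 in sparse and confluent VEC-positive cells. Top2a had 1.70, Mcm3 1.60 and Cdc6 1.54. Cholesterol synthesis genes had a negative interaction in 12 of 17 members and a positive one in 0 (median -1.26, percentile 0), with Fdps at -2.60 and Msmo1 at -2.52. Matrix proteases and inhibitors had a negative one in 8 of 11, with Plat at -3.17, and extracellular matrix genes in 11 of 26 against 3 positive. Notch genes were negative in 5 of 12, with Dll4 at -3.14 and Notch4 at -2.18. Vascular growth factors were negative in 9 of 23 and positive in 3, with Igfbp3 at -2.74. Although Vwf was positive, endothelial identity genes were negative in 6 of 33 and positive in 3 (median -0.45, percentile 0.1). Tight junction genes were negative in 2 of 11 and positive in 1, Cldn5 (median -0.46, percentile 3.4). Of the 33 interferon genes, 6 were positive and 1 was negative, and the median was -0.04 at percentile 30.5. Adjusted over the list alone, the integrin and leukocyte adhesion list had 5 negative members in place of 4, and no other list changed its counts.

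**Figure D4:**
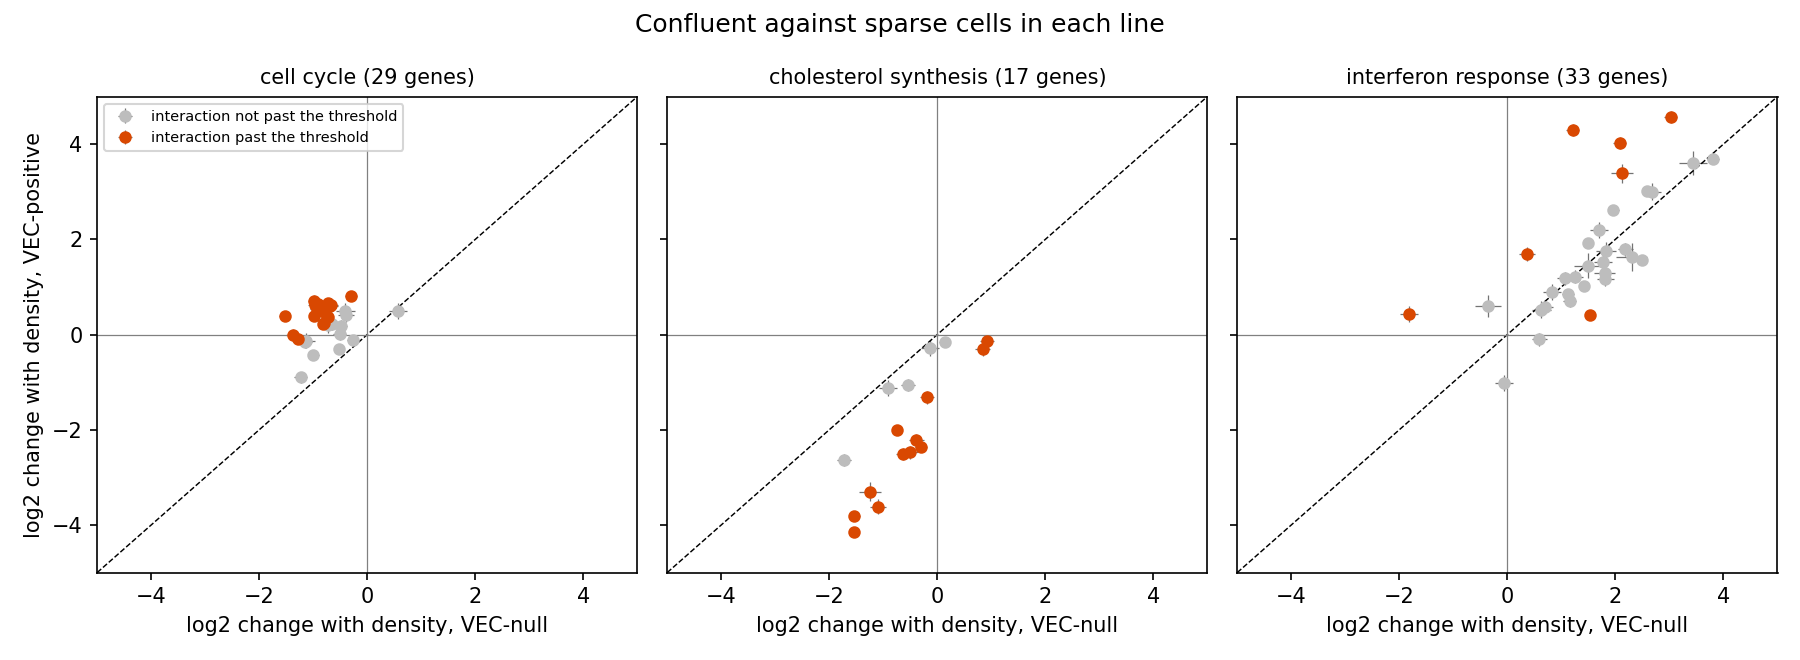
Log2 change from sparse to confluent in VEC-null (x axis) and VEC-positive cells (y axis) for each measured gene of 3 lists, with bars giving the SE, the dashed line marking equal responses and orange points the genes whose interaction passed. Of 29 cell cycle genes 16 are orange and lie above the line, and of 17 cholesterol synthesis genes 12 are orange and lie below it.

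The interaction was positive for 843 and negative for 902 of the 14301 probe sets, and 1018 passed with an offset of 200. After median centring 961 were positive and 843 negative. For Gas6 the sign depended on the offset, at 1.02 with the offset of 50 and -0.11 without an offset.

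In the fit with the 4 cRNA samples as units, which takes VEC and density as additive effects, 202 probe sets were higher and 118 lower in VEC-positive cells, 320 in all. Leaving out the second copy of sparse VEC-null cells lowered this number to 133. For density, 826 were higher and 590 lower in confluent cells, 1416 in all. The spread in this fit comes from the departure from additivity, with 1 residual degree of freedom per chip.

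For 1150 genes with kept probe sets on both chips, the changes on chip A and chip B correlated with r between 0.501 for the interaction and 0.694 for density in VEC-null cells. Of 87 genes that changed by at least 1 on chip A between the lines in confluent cells, 84 (96.6%) had the same sign on chip B. The share was 87% for VEC in sparse cells, 88% for density in VEC-positive cells, 94.8% for density in VEC-null cells and 84.4% for the interaction.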

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

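The tests that count independent lines, that look for exchanged dishes and that look for exchanged lines were chosen after the result was seen, while the tests on the other chip and under quantile normalisation were fixed beforehand, except that counting each gene once was settled afterwards. The results here drew attention because the VEC effect differed between sparse and confluent cells in a test of that difference (the limma interaction), which 1745 probe sets passed. The values are the VEC effect in confluent minus that in sparse cells on the log2 scale.

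Among genes that were higher in VEC-positive cells, the effect was larger in confluent cells for Cldn5 (5.36), Vwf (4.65), Lamb3 (4.35), Slc14a1 (2.76), Sned1 (2.47), H1f10 (1.9) and AU021092 (1.81). It was larger in sparse cells for Krt19 (-4.12), Anxa8 (-3.3), Stfa3 (-3.29), cyclin D2 Ccnd2 (-2.21), Apbb1ip (-1.76) and gelsolin Gsn (-1.38). Among genes that were lower in VEC-positive cells, the fall was larger in confluent cells for Btnl9 (-4.27), Adamtsl1 (-3.7), Postn (-3.54), Col3a1 (-3.34), Igfbp3 (-2.74), Pmepa1 (-1.35) and Mest (-1.29). The fall was larger in sparse cells for the interferon-induced genes Ifit1 (3.09), Oasl1 (1.49) and Rsad2 (1.23), the chemokine Ccl5 (2.31), Slc6a15 (2.43) and Gja1 (1.7). In VEC-positive cells Gja1, Pmepa1, Mest, Btnl9 and Postn had mean signals of 50.05 or less at both densities, near or under the offset, so that their values follow the levels in VEC-null cells. Another probe set of H1f10 gave a VEC effect of 0.01 in confluent cells, and another of Pmepa1 gave -1.77 in confluent and 0.17 in sparse cells.

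Cldn5, Vwf, Lamb3 and the other genes of the set that was highest in confluent VEC-positive cells were weighed first. Chip B was hybridised apart from chip A with the same cRNA. Of 24 set genes with a kept probe set on the other chip, 21 (87.5%, exact 95% interval 67.6% to 97.3%) rose there in all 3 comparisons. Of 1126 other genes, under the same level filter, 26.6% did so on chip A and 20.5% on chip B. For the genes covered, this argues against an error of single arrays or probe sets. Probe sets that stayed dim on the other chip were left out, while a rise in confluent VEC-positive cells could itself pass the filter. The 87.5% may therefore be too high for the set as a whole. Cldn5 and Vwf had no kept probe set on the other chip. After quantile normalisation 94.7% of the set's probe sets were still counted, which argues against array scaling. The design has 1 independent line per genotype, so that VEC at junctions and another difference between the lines cannot be told apart as the source of the set. An effect of VEC clustered at junctions stays open and was not tested, and RNA integrity stays open as well. The 3'/5' ratios were highest in this group for Gapdh on chip B and actin on chip A but not for actin on chip B. For Gapdh on chip A they were 1.01 and 0.968 in this group and at most 0.987 on the other arrays.

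Cell cycle genes, with Bub1, Top2a, Mcm3 and Cdc6 among the examples, had a median log2 change with density of -0.80 in VEC-null and of 0.37 in VEC-positive cells. All of the 16 members that passed the interaction (100%) still passed after quantile normalisation, which argues against array scaling. The YAP targets argue against exchanged sparse and confluent dishes of a line, since Ccn1, Ccn2 and Ankrd1 fell with density in both lines and the smallest of their 6 changes was -3.55. Exchanged lines at a single density would turn the line differences round, but of the probe sets that passed at both densities only 6.27% went opposite ways. A different growth state of the lines at the time of lysis and an effect of VEC on division both stay open, and neither was tested.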

How the results depend on the processing

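Leaving out the genes of chromosomes 5, 8, 10 and 14, together with probe sets that had no chromosome assigned, was the 1 alternative chosen after the data were seen. In each count that follows, the order is the VEC effect in confluent cells, the VEC effect in sparse cells, density in VEC-positive cells, density in VEC-null cells, the interaction, the set highest in confluent VEC-positive cells, and VEC and density with cRNA samples as units, where the values reported were 1131, 1388, 2194, 2356, 1745, 189, 320 and 1416. An offset of 200, which shrinks log changes of dim genes, gave 590, 689, 1305, 1444, 1018, 109, 203 and 911. Adjusted p alone gave 4708, 5540, 6793, 6666, 4078 and 914 for the first 6, and a minimum fold of 1.5 gave 2985, 3658, 4749, 4798, 3558 and 536, because the threshold is lower. Chip A alone gave 584, 670, 1120, 1207, 1010, 90, 68 and 596, and chip B alone gave 541, 711, 1063, 1144, 698 and 98, with 248 and 767 for VEC and density with cRNA samples as units. Fewer probe sets were tested on each chip alone, which does not account for the 68 on chip A, and that cause was not tested. A filter at the 75th percentile gave 699 and 920 for VEC in confluent and sparse cells and 114 for the set. Calls without a test, with each array pair at least 2-fold apart, gave 739 and 870 for VEC, 788 for the interaction and 124 for the set. Without the 4 chromosomes and the probe sets with no chromosome (27.7% fewer probe sets together), the counts were 708, 912 and 123 for VEC in confluent cells, in sparse cells and the set. The VEC effect with cRNA samples as units was 159 without the same probe sets, 197 without an offset, 207 after quantile normalisation, 163 after median centring and 183 without a variance trend, and the cause was not tested. Leaving out array copies in turn, where the lone copy is assumed to vary like the other groups, gave 1089 to 1193, 1365 to 1505, 2182 to 2287, 2328 to 2390, 1632 to 1795, 170 to 195, 133 to 385 and 1211 to 1534, with 133 without the second copy of sparse VEC-null cells. With the replicate number as a block the counts were 1133, 1389, 2196, 2362, 1746 and 188, but copy numbers did not pair the arrays (r -0.089 to 0.078 on chip A). For the named genes, 9590 of 9897 values under an alternative (96.9%) kept direction and side of the threshold, 208 no longer passed, 32 passed newly, 66 that passed neither way changed sign, and among those that passed 1 turned, the interaction of Gas6, at -0.11 without an offset. The 9590 include 588 values with the replicate block, which cannot change direction, and 4559 from leaving out an array copy. A gene whose probe set was not kept under an alternative was not counted there. The thresholds, variance trend, single chips, fits of only the groups compared, calls without a test and chromosomes were left out of this count and of the list medians. Of 2035 list medians, 1437 moved by less than the spread between copies, 595 (29.2%) moved by more and 3 turned. The 1437 include 120 medians with the replicate block, which leaves group means unchanged in this balanced design. They also include 765 from leaving out an array copy, where comparisons without that copy's group keep their medians. The share of 29.2% is lowered by these settings. A median counted as turned only if its reported percentile lay outside the range used above for random lists. Sign changes of other list medians are therefore not among the 3. The smooth muscle and fibroblast markers turned with density in VEC-null cells (0.02 with an offset of 200). The CDK inhibitors turned in the interaction (-0.03 without an offset and -0.09 with the filter at the 75th percentile). The cause was not tested for the turned medians. Without detection calls, the noise of dim probe sets limits what can be said of signals under the offset of 50.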

Other observations

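The comparison of chromosome medians between VEC and density comparisons, and the correlation without chromosomes 5, 8, 10 and 14, were chosen after the result was seen. So was the place where chromosome 10 was split. The tests on neighbouring genes and on imprinted genes were fixed before their results were seen.

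Gja1, Col5a2, Ak1, Sox11 and Mest differed between the lines at both densities, and of the 367 probe sets that passed at both, 344 went the same way. Neighbouring genes on a chromosome shared the VEC effect averaged over both densities with a correlation of 0.148 over 8925 pairs, where 1000 shuffles gave -0.031 to 0.031, and without chromosomes 5, 8, 10 and 14 it was 0.061. The density effect also had a neighbour correlation above its shuffles (0.082, against -0.039 to 0.033), so that part of the 0.148 may need no difference in copy number. The chromosome medians reached 0.43 (chromosome 10, a 1.35-fold shift with 75.7% of genes above 0, and 0.5 on chip A and 0.36 on chip B). In the density comparisons on the same arrays the largest was 0.12, which argues against scaling or hybridisation that differed between the densities of a line. A difference in hybridisation shared by all arrays of a line would cancel in the density comparisons, so they cannot show it. On chromosome 10 the first 120 measured genes in order had medians of -0.05 and -0.08 in confluent and sparse cells, and the remaining 316 had 0.63 and 0.53. A candidate explanation is a gain or loss of chromosomes or large segments in a line, and no DNA was measured to test it.

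Mest and Gatm are imprinted, and with Plagl1 they prompted a test of imprinted genes as a group. Over the 19 imprinted genes measured without these, the median size of the VEC effect was 0.55 in confluent and 0.5 in sparse cells, against 0.31 and 0.36 for all genes, which is percentile 97.9 and 90.8 of matched random lists. An imprinting difference between the lines may contribute, but the test decided neither way, since 90.8 lay between the bounds set beforehand for the lower of both percentiles.

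The connexin genes Gja1 and Gja4 were picked as a pair after the values were seen, and both were lower in VEC-positive cells when confluent. Gja1 (connexin 43) was at 7955 and 2289 in sparse and confluent VEC-null cells and at or under 23.7 in VEC-positive cells at either density. Gja4 (connexin 37), found in arterial endothelium, rose with density only in VEC-null cells, from 12.2 to 661, as did the Notch ligand Dll4 by 3.32 on the log2 scale, and the interaction was -3.35 for Gja4 and -3.14 for Dll4.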
